A study of Mus musculus with 10 samples.

How the data were processed

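Female germ cells carrying an Oct4-EGFP reporter were sorted by fluorescence from the gonads of mouse fetuses at E14.5 (embryonic days), per the labels, and bulk RNA was sequenced from 10 libraries: 4 Taf4b-deficient, 4 Taf4b-heterozygous and 2 Taf4b-wildtype. The labels call the deficient genotype infertile and both others fertile, and give each library 1 of 3 litter dates in 2019. They do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

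Reads were trimmed with Trim Galore 0.5.0, checked with FastQC 0.11.5, aligned to GRCm38 with HISAT2 2.1.0 and handled with SAMtools 1.9, per the submitters' processing notes. The deposited table of gene counts came from featureCounts (Subread 1.6.2) and the deposited TPM values from StringTie 1.3.3b, per the same notes, which name the tools but not their settings. The strand setting and the annotation release were not given in the sources used here. A table of DESeq2 output was also deposited by the authors, per the file headers. In the deposited DESeq2 table the authors give, per the file headers, a mean normalized count per gene (a signal made by dividing counts by size factors), a log2 fold change with its standard error, a test score, and a p-value with its adjusted form. The version of DESeq2 and the contrast behind that table were not given in the sources used here.

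The counts were used as deposited, all 55536 genes of the table were found by identifier in the GENCODE M21 annotation of GRCm38, and no reads stood outside named genes. Library totals ran from 28949924 to 44166320 reads. Genes were kept by edgeR's filterByExpr with genotype as the group, which left 20317. Scaling was TMM, and 1 edgeR 4.0.16 quasi-likelihood model with 3 genotype groups was fitted over the 10 libraries in R 4.3.3. Deficient libraries were compared with heterozygous, with wildtype, and with the equally weighted mean of both fertile genotypes, and heterozygous libraries with wildtype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Adjusted p-values of genes come from edgeR unless another tool is named. CPM values are read counts scaled by the library's reads in tested genes times its TMM factor, given as mean ± SD. SE is the standard error of the fitted log2 fold change, derived from the F statistic of the test. The 95% intervals of log2 fold changes use a normal multiple of SE, so they are narrower than the quasi-likelihood test itself would give.

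Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. Adjustment ran over the 26 lists of a comparison that had at least 5 tested members. A further list, of genes of the adult oocyte-to-embryo transition, had 2 tested members and was left out. The lists cover germ cell programmes, cell division, metabolism, ribosomal proteins, histones and markers of other cells the sort could hold. The design, the alternatives marked as planned, the gene lists and the naming rule were fixed before the data were examined. The naming rule took Taf4b; up to 10 called genes per direction with the largest fold, a mean of at least 5 CPM and an assigned symbol; per list and comparison up to 4 called members, or the 2 with the smallest p where none was called; and 15 germ cell and TFIID genes chosen in advance. The genes Gm8226, Gm49450, Aars2, Lars2, Gm23935, Csf1r, Coro1a and Cd52 fall outside this rule and were chosen after their values were seen, and Ddc and Sp3os are named because the authors' deposited table calls them. A gene that the rule took is not reported here, and it was left out of the search for outlying libraries.

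Alternatives covered scaling (DESeq2 size factors, upper quartile, totals), the filter on low counts, the tool (DESeq2 1.42.0, limma voom with sample weights, robust edgeR), litter date or replicate number as a term, a fit of only the groups compared, stricter thresholds, TPM with limma at pseudocounts of 0.1 and 1, and leaving out each library in turn. Those chosen after seeing the data were a covariate of meiotic stage, a covariate of reads resembling ribosomal RNA, surrogate variables from sva 3.50.0, leaving out groups of doubted libraries, upper quartile scaling of the lists, and DESeq2 with the fertile libraries pooled. When a wildtype library is left out, 1 wildtype sample remains, which edgeR assumes to vary like the other groups.

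The gene test was checked on simulated counts drawn from the real means and library sizes. Of the genes changed 2-fold it recovered 13.6% in the deficient against heterozygous comparison (19810 genes), 4.55% against wildtype (19779 genes), 29.9% against the fertile genotypes (19729 genes) and 6.25% in heterozygous against wildtype (19744 genes). At 4-fold these shares were 55.6%, 56.3%, 74.2% and 50.0%, and at 1.5-fold none was recovered. Unchanged genes called in error numbered 2, 4, 5 and 3 in the 4 simulated comparisons. An adjusted p threshold admits errors in proportion to all calls, and the simulations held many genes changed on purpose. These numbers therefore do not estimate the errors among the far fewer real calls. A simulated list of 50 genes raised 1.25-fold was called in the 4 comparisons under both correlations, and none of 25 unchanged lists was called. Genes were simulated as independent, so this does not test lists whose members vary together, as members of the real lists do (estimated correlation 0.718 for cytosolic ribosomal proteins).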

Results

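Transcriptomes were measured in oocytes of the mouse fetal ovary at E14.5 (embryonic days), the time at which female germ cells leave mitosis and enter meiosis. The question posed by the design is how these cells differ when Taf4b is missing. Taf4b encodes a gonad-enriched subunit of TFIID, the general transcription factor that places RNA polymerase II at promoters. Totals in the count table were 32120027, 37739826, 31867705 and 37213245 reads for deficient replicates 1 to 4, 35512743, 38052378, 44166320 and 28949924 reads for heterozygous replicates 1 to 4, and 31122690 and 30040675 reads for wildtype replicates 1 and 2. Litters of January 29 gave deficient replicates 1 and 2, heterozygous replicate 4 and wildtype replicate 1. Those of March 1 gave deficient replicate 3 and wildtype replicate 2, and those of March 7 gave deficient replicate 4 and heterozygous replicates 1 to 3. No pair of libraries matched within sampling noise, since the lowest chi-square per degree of freedom over a pair was 6.81. Correlations of log CPM across genes, which are not independent replicates, ran from 0.9505 to 0.987 within genotypes and from 0.945 to 0.985 between them.

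The targeted gene separated the deficient libraries from the others. Taf4b (ENSMUSG00000054321; chromosome 18, 14783245 to 14900359, plus strand of GRCm38, 15 exons in its longest transcript by exon number) stood at 56.1, 62.1, 65.0 and 60.1 CPM in the deficient libraries. It stood at 144, 223, 195 and 234 CPM in the heterozygous libraries and at 152 and 207 CPM in the wildtype libraries. The group means were 60.8 ± 3.71 CPM (SD, n = 4), 199 ± 40.3 CPM (SD, n = 4) and 180 ± 38.7 CPM (SD, n = 2), so deficient libraries held 30.5% of the heterozygous and 33.8% of the wildtype level. Heterozygous and wildtype libraries differed in Taf4b by a log2 fold change of 0.15 (SE 0.20, adjusted p = 0.868, 95% interval -0.24 to 0.54). Within each of the 3 litter dates every deficient library lay below every fertile library. The labels do not state which part of the gene was removed, so reads from remaining exons may count toward the deficient values. The pseudogene AC133172.1 lies within the gene on the same strand. Whether its reads enter the Taf4b count is unknown, since the settings of the counting were not given.

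**Figure D1:**
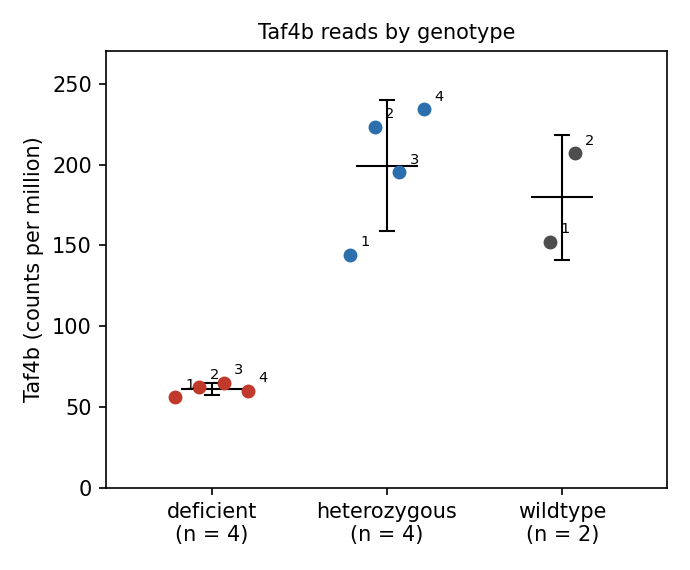
Taf4b in CPM (vertical axis) in each library, by genotype (4 deficient, 4 heterozygous, 2 wildtype); points are libraries, and bars give the mean ± SD. The deficient libraries lie between 56.1 and 65.0 CPM, below the lowest fertile library at 144 CPM.

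Genes of meiotic progression varied widely between libraries of 1 genotype. Dazl and Ddx4, which encode RNA-binding proteins of germ cells, stood at 2543 ± 198 and 892 ± 99.5 CPM in deficient, 2487 ± 179 and 959 ± 179 CPM in heterozygous (SD, n = 4 each) and 2506 ± 169 and 876 ± 98.7 CPM in wildtype libraries (SD, n = 2). Stra8, which drives entry into meiosis, stood at 621 ± 309, 682 ± 308 and 599 ± 15.1 CPM. The mean log2 CPM of the meiotic recombination list was 5.44, 5.84, 4.55 and 5.16 in deficient replicates 1 to 4, 4.35, 6.38, 6.13 and 6.15 in heterozygous replicates 1 to 4, and 5.45 and 5.43 in the wildtype replicates. The pluripotency and early germ cell list ran the other way, at 5.39, 4.97, 6.14 and 5.53 in deficient, 6.07, 4.597, 4.74 and 4.72 in heterozygous, and 5.63 and 5.24 in wildtype libraries. The recombination level minus the pluripotency level averaged -0.26 ± 1.02 in deficient and 0.72 ± 1.64 in heterozygous libraries (SD, n = 4 each; two-sided exact permutation p = 0.314 over 70 arrangements). Within the January date this difference was 0.04 and 0.86 in deficient replicates 1 and 2, 1.43 in heterozygous replicate 4 and -0.19 in wildtype replicate 1. Within March 1 it was -1.59 in deficient replicate 3 and 0.19 in wildtype replicate 2, and within March 7 it was -0.36 in deficient replicate 4 against -1.72, 1.79 and 1.40 in heterozygous replicates 1 to 3. Principal component 1, with 36.9% of the variance, placed heterozygous replicate 1 at -56.3 and the other heterozygous libraries between 52.8 and 69.7. Lars2 and Gm23935, whose reads can stem from ribosomal RNA, were low in deficient replicates 2 and 4 and heterozygous replicate 3; Gm23935 stood at 454, 141 and 87.4 CPM there and from 4146 to 5068 CPM in the other libraries.

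**Figure D2:**
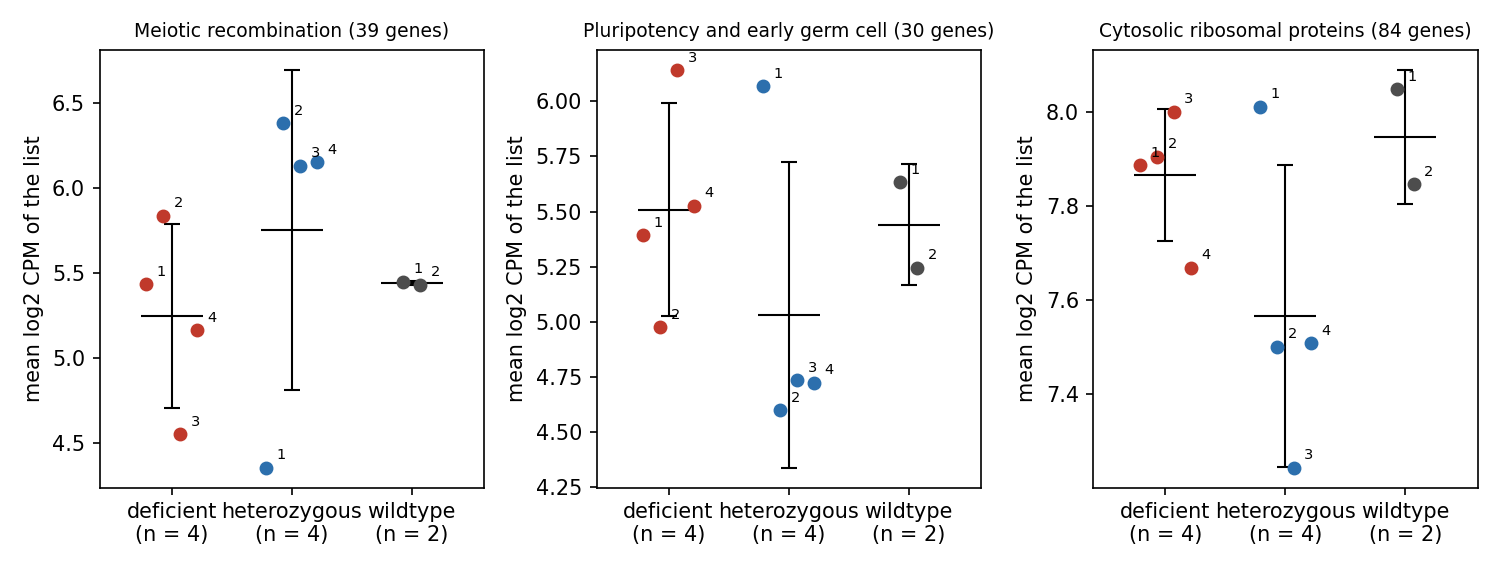
Mean log2 CPM (vertical axes) of the meiotic recombination, pluripotency and early germ cell, and cytosolic ribosomal protein lists in each library, by genotype (4 deficient, 4 heterozygous, 2 wildtype); points are libraries, and bars give the mean ± SD. Heterozygous replicate 1 lies at 4.35 for recombination and 6.07 for pluripotency, while the other heterozygous libraries lie from 6.13 to 6.38 and from 4.597 to 4.74.

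Deficient against heterozygous libraries asked what the loss of the second Taf4b copy changes. Taf4b fell by 1.71 on the log2 scale (SE 0.17, 3.28-fold lower, adjusted p = 0.0118, n = 4 and 4), lower in 4 of 4 deficient libraries. Genes of cytosolic ribosomal proteins rose as a group under the preset correlation but not with an estimated one (adjusted p = 0.899), with 75 of 84 members higher and a median log2 fold change of 0.29. Heterozygous replicate 1 did not share this difference, since the list's mean log2 CPM was 8.01 there, 7.24 to 7.51 in the other heterozygous libraries and 7.6688 to 8.0004 in the deficient libraries. Under the preset correlation alone, genes of the pluripotency and early germ cell state rose with a median of 0.49 (27 of 30 higher), and meiotic recombination genes fell with a median of -0.61 (31 of 39 lower). Genes of the blood and macrophage list rose with a median of 0.85 (15 of 21 higher), again under the preset correlation alone and from a heterozygous mean of -0.64 log2 CPM. The call counts were 2 higher genes and 1 lower gene of 20317. The higher genes were a processed pseudogene and a predicted gene. Gm8226 (ENSMUSG00000099927; chromosome 9, 84423984 to 84424781, plus strand, a processed pseudogene with 1 exon) stood at 1.84 ± 0.154 CPM in deficient, 0.350 ± 0.069 in heterozygous (SD, n = 4 each) and 2.13 ± 0.352 CPM in wildtype libraries (SD, n = 2), a log2 fold change of 2.38 (SE 0.26, adjusted p = 0.0162). Gm49450 (ENSMUSG00000116358; chromosome 15, 98932137 to 98953551, minus strand, 4 exons) stood at 9.63 ± 0.914, 3.15 ± 0.329 and 10.3 ± 2.94 CPM, a log2 fold change of 1.61 (SE 0.20, adjusted p = 0.0322). It overlaps the alpha tubulin genes Tuba1a and Tuba1b on its own strand and Gm41396 and Gm49449 on the other, so its reads are uncertain, and in the deposited TPM values its direction was reversed (-1.91 with a pseudocount of 0.1). A pseudogene such as Gm8226 can also share reads with its parent gene, and in the deposited TPM values its change was smaller and not called (0.62 with a pseudocount of 0.1, adjusted p = 0.06295).

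Of the 26 lists tested, 9 rose and 1 fell with the preset correlation, and each of these calls was lost with an estimated correlation (adjusted p = 0.899 for each). Cytosolic ribosomal proteins (adjusted p = 9.18e-14) had 24 members with an unadjusted p under 0.05, led by Rpl6 at 464 ± 40.8 against 279 ± 81.2 CPM (log2 fold change 0.73, adjusted p = 0.297). Many of these genes have processed pseudogenes, so their counts are uncertain. The nuclear-encoded respiratory chain (adjusted p = 4.25e-07) had 60 of 73 members higher at a median of 0.14, among them the ATP synthase subunit gene Atp5g1 at 0.51 and the complex I subunit gene Ndufs4 at 0.38. In the mitotic G2 and M phase list (adjusted p = 6.03e-06; 45 of 54 higher, median 0.23), the mitotic kinesin Kif20a stood at 0.57 and the cyclin Ccnb2 at 0.52. Replication-dependent histones (adjusted p = 2.61e-05; 37 of 57 higher, median 0.35) included Hist1h2bg at 0.89 and Hist1h3e at 0.95. In the pluripotency and early germ cell list (adjusted p = 7.43e-05), the germ cell RNA-binding factor Nanos3 and the pluripotency marker Dppa5a each stood at 0.72, and the pluripotency factors Pou5f1 and Nanog stood at 0.50 and 0.49. The cholesterol biosynthesis (adjusted p = 0.0331, median 0.19), DNA replication (adjusted p = 0.0336, median 0.09) and glycolysis (adjusted p = 0.0399, median 0.19) lists also rose, with larger adjusted p-values. Among their members the sterol sensor Insig1 stood at 0.44, the replication clamp Pcna at 0.30 and its loader Rfc1 at 0.49. Gapdh went against its list at -1.44, from 13.7 ± 12.5 CPM to 5.06 ± 0.846 CPM, and its many pseudogenes make it uncertain.

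In the meiotic recombination list (adjusted p = 0.0399), Brca2, which loads recombinases, stood at -0.52, the meiotic chromatin factor Zfp541 at -1.61, and the recombinase Dmc1 at -0.61. Members of the meiotic cohesin, axis and synaptonemal complex list stood lower in 20 of 25 cases without a call (median -0.42, adjusted p = 0.206), with the cohesin Stag3 at -0.49, the telomere attachment gene Terb2 at -0.67, Sycp3 at -0.42 and Rec8 at -0.13. In the blood and macrophage list (adjusted p = 6.03e-06), 9 members were called when adjusted over the list alone and none over all genes. The complement gene C1qc stood at 2.15 ± 0.599 against 0.721 ± 0.195 CPM (log2 fold change 1.57, adjusted p = 0.287), and the Fc receptor gene Fcer1g at 1.497 ± 0.420 against 0.431 ± 0.137 CPM (1.80, adjusted p = 0.287). For fry, which does not compare with other genes, the smallest adjusted p was 0.338 for 1 direction and 0.0330 for either direction, the latter in this list. In the other called lists no member was called when adjusted over the list alone. The 16 remaining lists had adjusted p-values from 0.0823 to 0.911. Median, mean and test differed in sign in 6 of them, without a call: TFIID subunits and TBP relatives, meiotic initiation and signalling, oocyte differentiation and primordial follicle, premature ovarian insufficiency genes, mitochondrially encoded, and X-linked genes.

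Heterozygous replicate 1, the library with the lowest recombination and highest pluripotency level of its group, moved this comparison more than any other single library left out. Without it edgeR called 519 genes (306 higher and 213 lower), the meiotic cohesin, axis and synaptonemal complex list was called at adjusted p = 0.000183, and Taf4b reached adjusted p = 0.000723. Without deficient replicate 1, 2, 3 or 4, or heterozygous replicate 2 or 4, no gene was called, and without heterozygous replicate 3 the calls numbered 2. Adjusted p of Taf4b was then 0.0972, 0.0769, 0.0587, 0.0730, 0.0681 and 0.0625 for these 6 in turn, over a range of 4.11e-14 to 0.111 across the alternatives. Gm8226 lost its call without deficient replicates 1 to 4 (0.0972, 0.0769, 0.0689 and 0.0730) and heterozygous replicates 2 to 4 (0.127, 0.0586 and 0.130). Gm49450 lost its call without the same libraries (0.0972, 0.160, 0.0886, 0.139, 0.232, 0.0981 and 0.216). The log2 fold changes stayed at 2.29 to 2.46 for Gm8226 and 1.58 to 1.68 for Gm49450 in these fits. The meiotic recombination list lost its call without deficient replicates 3 and 4 (adjusted p = 0.361 and 0.0979), heterozygous replicates 2 to 4 (0.284, 0.422 and 0.129) and wildtype replicate 1 (0.0571). The DNA replication list lost its call without deficient replicates 3 and 4 (0.0592 and 0.124) and heterozygous replicates 2 and 4 (0.226 and 0.161), and the cholesterol biosynthesis list without the same libraries (0.0589, 0.257, 0.226 and 0.214). The glycolysis list lost its call without deficient replicates 1, 3 and 4 (0.0633, 0.139 and 0.171) and heterozygous replicates 2 to 4 (0.288, 0.157 and 0.248), and the replication-dependent histones list without heterozygous replicate 3 (0.0527). The lists of cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mitotic G2 and M phase, blood and macrophage, and pluripotency and early germ cell kept their calls without any 1 library under the preset correlation.

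DESeq2 called 170 genes and limma voom with sample weights 3012 in the same comparison, against 3 with edgeR. The voom weights were lowest for heterozygous replicates 1 and 3 (0.245 and 0.354) and highest for heterozygous replicate 4 (2.83). That fit therefore also differs from edgeR in how much each library counts. Without the 3 libraries low in Gm23935 edgeR called 97 genes (5 higher and 92 lower). With litter date as a term no gene was called by edgeR, Taf4b stood at -1.83 (adjusted p = 0.111), and the meiotic recombination list lost its call (adjusted p = 0.0921). At an unadjusted p under 0.05 there were 2421 genes (977 higher, 1444 lower) where chance gives 1015.85 for independent genes. Genes are not independent, and 7 of the 35 splits of these 8 libraries, the real one included, reached that number (highest other 6408). Groups did not overlap in 1213 genes (5.97%), where chance gives 2.86%.

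**Figure D3:**
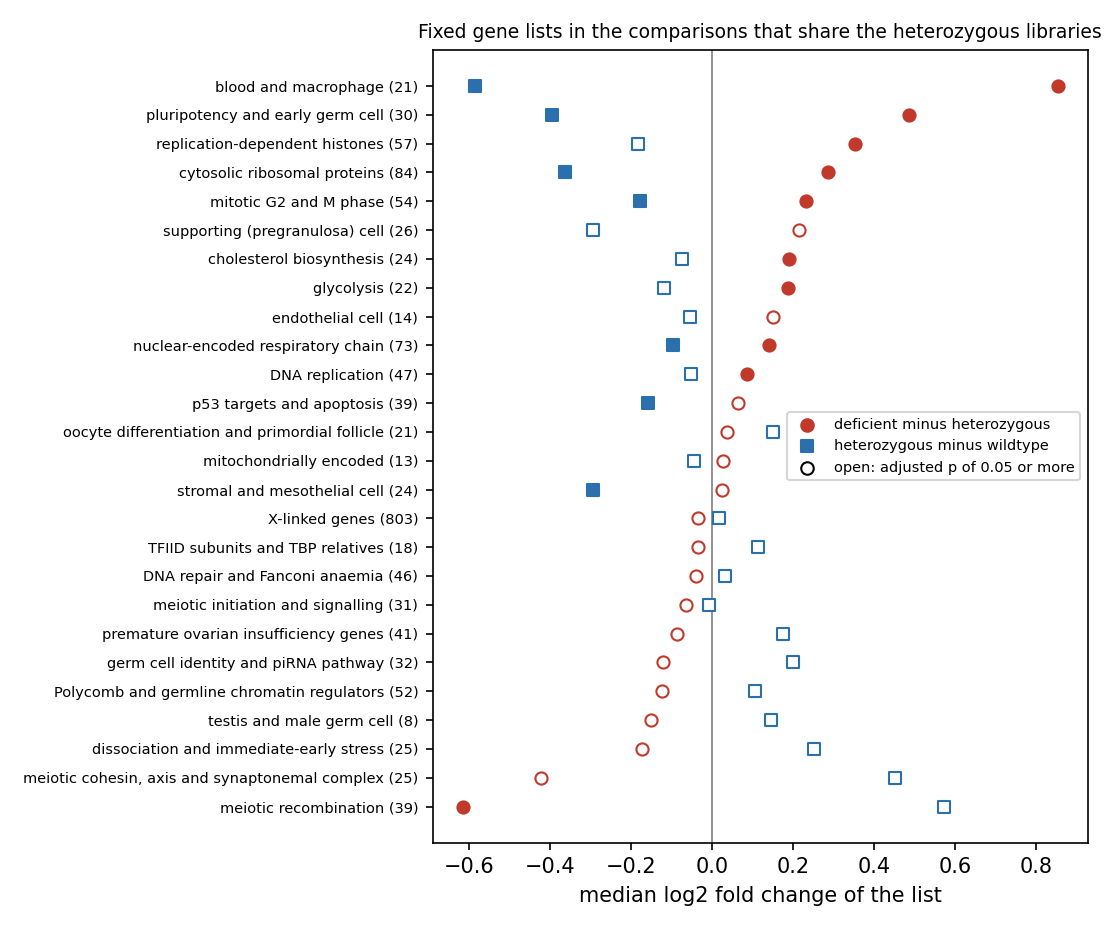
Median log2 fold change (horizontal axis) of the 26 gene lists, with the number of tested members in parentheses, for deficient minus heterozygous (circles, n = 4 and 4) and heterozygous minus wildtype (squares, n = 4 and 2); filled marks have a camera adjusted p under 0.05 with the preset correlation. The blood and macrophage list lies at 0.85 and -0.58 and the meiotic recombination list at -0.61 and 0.57; the 4 heterozygous libraries enter both comparisons with opposite sign, so chance in them moves a list's marks apart.

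Deficient against wildtype libraries compared the loss of Taf4b with the unaltered genotype. Taf4b stood at -1.56 on the log2 scale (SE 0.19, 95% interval -1.94 to -1.19, n = 4 and 2), lower in 4 of 4 deficient libraries, with adjusted p = 0.113 by edgeR. Of the immediate-early genes, the AP-1 subunit gene Jund stood at 27.4 ± 8.27 against 13.6 ± 3.24 CPM (log2 fold change 1.01) and Ier5 at 9.99 ± 1.14 against 5.80 ± 1.66 CPM (0.79), neither called. The TFIID subunit genes Taf5 and Taf10 stood at 0.84 and 0.74, the transcription factor genes Klf2 and Sox2 at 1.22 and 0.90, and the survival gene Mcl1 at 1.00. The ribosomal protein genes Rpl10 and Rps12 stood at -0.58 and -0.56. Adjusted p was 1.00 for each of these genes. Stra8 (0.05), Dmc1 (0.21), Pou5f1 (0.05), Nanog (0.03) and Dppa5a (0.03) stood close to wildtype. No gene was called by edgeR, while 743 (528 higher, 215 lower) had an unadjusted p under 0.05 where chance gives 1015.85. DESeq2 and limma voom with sample weights each called 1 gene, Taf4b, at adjusted p = 1.44e-06 and 0.00968, within a range of 1.44e-06 to 1.00 across the alternatives. Groups did not overlap in 2570 genes (12.6%), where chance gives 13.3%.

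None of the 26 lists was called in this comparison. The smallest adjusted p, 0.0783, was shared by the nuclear-encoded respiratory chain (60 of 73 higher, median 0.07), replication-dependent histones (38 of 57 higher, 0.16), dissociation and immediate-early stress (19 of 25 higher, 0.32), and stromal and mesothelial cell (17 of 24 lower, -0.27) lists. With an estimated correlation the smallest adjusted p was 0.937. Cytosolic ribosomal proteins stood lower in 61 of 84 cases (median -0.06, adjusted p = 0.204). The median (0.39) and mean (-0.34) of the blood and macrophage list differed in sign. Taf4b was called without heterozygous replicate 1 (adjusted p = 0.00731). Without wildtype replicate 1 the replication-dependent histones (adjusted p = 2.71e-09), nuclear-encoded respiratory chain (1.11e-06), mitotic G2 and M phase (0.00363) and dissociation and immediate-early stress (0.0110) lists were called, and without wildtype replicate 2 the cytosolic ribosomal proteins (0.000263) and supporting (pregranulosa) cell (0.0121) lists were called.

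Deficient libraries against both fertile genotypes addressed the infertile phenotype given in the labels. Taf4b fell by 1.64 on the log2 scale (SE 0.16, adjusted p = 0.0117, n = 4 and 6) and was the only gene called by edgeR, lower in 4 of 4 deficient libraries. Ddc, which encodes aromatic amino acid decarboxylase, stood higher in each deficient library than in any fertile one, at 30.2 ± 2.83 CPM against 18.3 ± 0.822 in heterozygous and 19.7 ± 0.239 CPM in wildtype libraries (log2 fold change 0.67, SE 0.12, adjusted p = 0.904). Aars2, the mitochondrial alanyl-tRNA synthetase gene, stood lower in each, at 24.3 ± 2.82 CPM against 37.2 ± 2.88 and 40.5 ± 0.225 CPM (-0.67, SE 0.13, adjusted p = 0.904). With the preset correlation 6 of 26 lists rose and none fell: nuclear-encoded respiratory chain (median 0.11, 64 of 73 higher, adjusted p = 4.08e-06), replication-dependent histones (0.31, 41 of 57, 3.68e-05), blood and macrophage (0.62, 15 of 21, 0.000105), cytosolic ribosomal proteins (0.13, 66 of 84, 0.000105), mitotic G2 and M phase (0.14, 44 of 54, 0.000174), and pluripotency and early germ cell (0.28, 28 of 30, 0.00177). Each call was lost with an estimated correlation (adjusted p = 0.899 for each). The rise of ribosomal proteins was not seen against wildtype alone, where 61 of 84 stood lower. In the blood and macrophage list 4 members were called when adjusted over the list alone, with C1qc at 1.23 and Fcer1g at 1.36. The mean of this list was only 0.02, far below its median of 0.62, and 6 of its 21 members stood lower. The meiotic recombination list stood at a median of -0.31 (31 of 39 lower, adjusted p = 0.0942).

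The Taf4b call against the fertile genotypes was lost without deficient replicates 1 to 4 (adjusted p = 0.125, 0.102, 0.0590 and 0.118) and wildtype replicate 2 (0.0753), and with litter date as a term (0.0665), over a range of 1.82e-17 to 0.847 across the alternatives. DESeq2 called 4 genes, Ddc and Aars2 among them, limma voom with sample weights called 1, and 875 genes had an unadjusted p under 0.05 (403 higher, 472 lower) where chance gives 1015.85. Groups did not overlap in 283 genes (1.39%), where chance gives 0.952%. Without wildtype replicate 2 the calls of cytosolic ribosomal proteins (adjusted p = 0.0885), mitotic G2 and M phase (0.0852), pluripotency and early germ cell (0.183) and replication-dependent histones (0.131) were lost, and without deficient replicate 3 that of pluripotency and early germ cell (0.413). Without heterozygous replicate 1 the meiotic recombination list was called (adjusted p = 1.94e-06) and the number of called lists was 11, and without deficient replicate 2 it was 12.

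Heterozygous against wildtype libraries compared carriers of 1 mutant copy with the unaltered genotype. This comparison used heterozygous replicates 1 to 4, which also enter the comparison with deficient libraries. Genes of cytosolic ribosomal proteins fell as a group under the preset correlation (adjusted p = 5.26e-16) but not with an estimated one (adjusted p = 0.834), with 78 of 84 members lower and a median of -0.36. Rpl23a stood at 52.6 ± 12.8 against 95.4 ± 11.3 CPM (log2 fold change -0.86, adjusted p = 0.243), Rpl10 at -0.83 and Rpl6 at -0.77, in n = 4 and 2 libraries. Cdkn1a, the cell cycle inhibitor induced by p53, stood at -0.73, while Klf2 stood at 33.4 ± 10.2 against 9.47 ± 2.35 CPM (1.82, adjusted p = 0.243), Mcl1 at 1.44 and Jund at 1.41. Gm8226 fell by 2.59 on the log2 scale (SE 0.29, 6.01-fold lower, adjusted p = 0.0465) and was the only gene called by edgeR. In the deposited TPM values it stood at -0.75 without a call (pseudocount of 0.1, adjusted p = 0.106). DESeq2 called 475 genes (419 higher, 56 lower) and limma voom with sample weights 1063. At an unadjusted p under 0.05 there were 1686 genes (1259 higher, 427 lower) where chance gives 1015.85, and groups did not overlap in 3215 (15.8%), where chance gives 13.3%.

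With the preset correlation 7 of 26 lists fell in heterozygous against wildtype libraries and none rose. Beside the ribosomal proteins these were blood and macrophage (median -0.58, 18 of 21 lower, adjusted p = 0.00108), mitotic G2 and M phase (-0.18, 45 of 54, 0.00728), pluripotency and early germ cell (-0.39, 26 of 30, 0.0111), nuclear-encoded respiratory chain (-0.10, 48 of 73, 0.0136), p53 targets and apoptosis (-0.16, 28 of 39, 0.0214), and stromal and mesothelial cell (-0.29, 18 of 24, 0.0214). Each call was lost with an estimated correlation (adjusted p = 0.834 for each). In the blood and macrophage list C1qa stood at -1.40 and C1qb at -0.98, and in the stromal and mesothelial cell list the matrix gene Mgp stood at -1.49 from below 1 CPM. No member of the 7 lists was called when adjusted over its list alone. The dissociation and immediate-early stress list was not called (median 0.25, adjusted p = 0.0671), with 3 members called when adjusted over the list alone. It was called in 7 alternatives and not in 13. Its mean log2 CPM was 4.77 and 4.49 in heterozygous replicates 1 and 3, 3.91 and 3.84 in replicates 2 and 4, and 3.86 and 3.66 in wildtype libraries. The meiotic recombination list stood at 0.57 (35 of 39 higher, adjusted p = 0.228).

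The Gm8226 call in heterozygous against wildtype libraries was lost without any 1 of the 10 libraries, at adjusted p from 0.0615 to 1.00, while its log2 fold change stayed between -2.80 and -2.41. List calls were lost without wildtype replicate 1 for mitotic G2 and M phase (adjusted p = 0.548), nuclear-encoded respiratory chain (0.919), p53 targets and apoptosis (0.174) and pluripotency and early germ cell (0.411), and without wildtype replicate 2 for stromal and mesothelial cell (0.141). Without heterozygous replicate 2 mitotic G2 and M phase (0.0730), p53 targets and apoptosis (0.0703) and pluripotency and early germ cell (0.128) lost their calls. Pluripotency and early germ cell was also lost without heterozygous replicates 3 (0.0903) and 4 (0.0923), stromal and mesothelial cell without heterozygous replicates 1 (0.178) and 3 (0.0903), and nuclear-encoded respiratory chain without heterozygous replicate 4 (0.0597). Without heterozygous replicate 1 the meiotic recombination (5.62e-06) and meiotic cohesin, axis and synaptonemal complex (0.00134) lists were called.

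X-linked genes made up 803 of the 20317 tested (3.95%), and none was among the edgeR calls of the 4 comparisons. DESeq2 called 12 X-linked genes in deficient against heterozygous and 15 in heterozygous against wildtype libraries. At an unadjusted p under 0.05, X-linked genes made up 47 of 977 higher and 38 of 1444 lower genes in the former comparison (odds ratios 1.24 and 0.64, Fisher's exact test, adjusted p = 0.204 and 0.0247 over 8 tests). In the latter they made up 23 of 1259 higher and 26 of 427 lower genes (odds ratios 0.44 and 1.59, adjusted p = 0.000144 and 0.0629). The test takes genes as independent, which they are not.

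The authors' deposited table lists 21049 genes, of which 3 have an adjusted p under 0.05. In the authors' deposited table Taf4b stands at -1.66 (SE 0.19, adjusted p = 1.25e-13, DESeq2), Ddc at 0.69 (adjusted p = 0.00177) and Sp3os at 0.50 (adjusted p = 0.0236), and Aars2 stands at -0.62 (adjusted p = 0.0624). Sp3os (chromosome 2, 72979424 to 72988677, plus strand, 3 exons) is antisense to and overlaps Sp3, a transcription factor gene, and with an unstated strand setting reads of the pair cannot be assigned. In the counts Sp3os stood at 32.9 ± 2.36 CPM in deficient, 24.3 ± 1.03 in heterozygous and 22.9 ± 1.21 CPM in wildtype libraries, with a log2 fold change of 0.48 against the fertile genotypes (SE 0.12, edgeR adjusted p = 0.904). Ddc lies on chromosome 11 (11814101 to 11898144, minus strand, 15 exons) and Aars2 on chromosome 17 (45506841 to 45520843, plus strand, 22 exons). Over the 20236 shared genes the log2 fold changes in the authors' deposited table correlated with the contrast against both fertile genotypes at r = 0.944, with heterozygous alone at r = 0.872 and with wildtype alone at r = 0.638, across genes that are not independent replicates. Of these genes 92.7% had the same sign as in the contrast against both fertile genotypes, and 1 gene, Taf4b, was called in both. With the 6 fertile libraries pooled as 1 group r was 0.954 in edgeR. DESeq2 on the pooled libraries, a test chosen after the data were seen, called 7 genes, among them Taf4b, Ddc and Sp3os, the 3 genes called in the authors' deposited table.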

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

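Each gene, list or library measure was examined in the deficient and in the heterozygous group, which made 206 tests. Of these, 26 held a library whose gap to its nearest neighbour took up most of the range of its group. Chance gives about 1 in 20 for independent tests. These tests are not independent, since lists, their members and principal component 1 overlap, so 1 pattern can be counted many times. The tests of litter date, reads resembling ribosomal RNA, ovarian somatic cells and genotype for the first pattern, of ribosomal protein pseudogenes and of gene length alone for the second, of macrophage markers with 2 genes added for the third, and the splits of the libraries were chosen only after the result was seen.

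Heterozygous replicate 1 accounted for 18 of the 26. It stood above the other heterozygous libraries in Dppa5a (361 against 120 to 141 CPM), Pou5f1 (122 against 36.1 to 45.2), Nanog (89.4 against 13.8 to 21.6), Sox2 (66.8 against 26.0 to 27.8), Insig1 (171 against 87.3 to 99.0), Rfc1 (159 against 107 to 115), Ndufs4 (166 against 136 to 140), Rpl6 (399.99 against 231 to 252) and Gm49450 (3.64 against 2.93 to 3.04), and below them in Figla (2.30 against 33.6 to 38.5) and Coro1a (1.75 against 3.46 to 3.79). Its mean log2 CPM was lower in the lists of meiotic recombination (4.35 against 6.13 to 6.38), meiotic cohesin, axis and synaptonemal complex (5.28 against 6.79 to 7.05) and germ cell identity and piRNA pathway (5.95 against 6.78 to 6.91). It was higher in those of pluripotency and early germ cell (6.07 against 4.597 to 4.74) and p53 targets and apoptosis (4.43 against 4.10 to 4.15). The recombination minus pluripotency difference was -1.72 against 1.40 to 1.79, and principal component 1 was -56.3 against 52.8 to 69.7.

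Heterozygous replicate 3 stood below the other heterozygous libraries in Gm23935 (87.4 against 4503 to 4756 CPM), Lars2 (634 against 12026 to 12316), the mitochondrially encoded list (mean log2 CPM 6.15 against 7.62 to 7.89), the share of reads in mitochondrial coding genes (0.440% against 1.09% to 1.18%) and the DNA repair and Fanconi anaemia list (6.25 against 6.34 to 6.35). Heterozygous replicate 4 stood above the others in Hbb-y (1.42 against 0 CPM), Mgp (0.474 against 0.154 to 0.204) and Nobox (1.52 against 1.03 to 1.08).

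The first pattern is the spread of meiotic progression within genotypes, with heterozygous replicate 1 and deficient replicate 3 at the pluripotent end. Litter date is argued against, since libraries of 1 date covered 100% of the whole range of the recombination minus pluripotency difference. Reads resembling ribosomal RNA showed no clear relation to it (Pearson r = -0.250, permutation p = 0.497, Spearman rho = -0.115, p = 0.760, r = -0.235 without the 2 farthest libraries, n = 10). Ovarian somatic markers showed none either (r = 0.126, p = 0.723, rho = 0.0788, p = 0.839, r = 0.197 without the 2 farthest). Over these 2 relations the permutation tests gave adjusted p = 0.723 for both r values and adjusted p = 0.839 for both rho values. With 10 libraries a moderate relation cannot be excluded for either. Genotype remains open, since the deficient and heterozygous means cannot be told apart with 4 libraries each (-0.26 against 0.72, exact permutation p = 0.314). A hypothesis left untested is that fetuses of 1 nominal age differed in developmental timing, which the labels do not record.

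The second pattern is the higher level of ribosomal protein, respiratory chain and histone genes in deficient than in heterozygous libraries. The medians of 0.285, 0.1401 and 0.353 lay above 100%, 99.6% and 100% of 10000 random lists matched on exon length. With length and expression level both matched, ribosomal proteins (0.0986 to 0.203 in 95% of lists, above 100%) and histones (-0.132 to 0.150, above 100%) still lay above. For the respiratory chain length and level together stay a candidate explanation (0.120 to 0.235, above 13.1%). Members of the real lists vary together (estimated correlations of 0.718, 0.311 and 0.286 for ribosomal proteins, respiratory chain and histones). The random lists were not matched on this, so their ranges may be too narrow. The tests therefore cannot exclude gene length or level as the cause. Reads shifted from processed pseudogenes stay open for ribosomal proteins, because the 131 pseudogenes had a median of 0.0870 with an interval that included 0 (-0.0129 to 0.154). Meiotic stage, the first pattern, also stays open for ribosomal proteins. Their mean log2 CPM was 8.01 and 8.0004 in heterozygous replicate 1 and deficient replicate 3, the least advanced libraries. It was 7.24 to 7.51 in heterozygous replicates 2 to 4, the most advanced, but highest in wildtype replicate 1, of middle stage. The stage covariate ended their call against the fertile genotypes and not against heterozygous libraries. An effect of genotype also stays open, but chance could not be excluded: 17 of 35 splits of the 8 libraries called at least the 10 lists of the real split (highest other 15), and 78 of 100 did for the 6 lists of the contrast with the fertile genotypes (highest other 16).

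The third pattern is the higher level of macrophage genes in deficient than in heterozygous libraries. Macrophages carried through the sort for GFP may explain it. From the fixed list 13 markers were picked after its result was seen, leaving out Coro1a, Cd52, and the haemoglobin and red cell genes. Of these 13 markers 12 stood higher, while 6 of the 21 tested members of the whole list stood lower. The 13 markers varied together within genotypes at a mean pairwise r of 0.451, against -0.0564 to 0.154 in 1000 matched sets. With Coro1a and Cd52 added, at log2 fold changes of 0.33 and 0.85, the mean r was 0.421. The highest mean level of the 13 markers over the 10 libraries was 3.11 CPM. That marker was Csf1r, the macrophage growth factor receptor gene, at 4.37 ± 1.29 CPM in deficient, 1.72 ± 1.01 in heterozygous (SD, n = 4 each) and 3.36 ± 0.299 CPM in wildtype libraries (SD, n = 2). Against wildtype the blood and macrophage list was not called (camera with the preset correlation, adjusted p = 0.277), and it was called lower in heterozygous than in wildtype libraries. The pattern may thus be a low level in heterozygous libraries. With litter date as a term the call against heterozygous libraries was kept under the preset correlation, while chance was not tested for this list by itself. Whether the ovaries differ in macrophages, or the sort let differing numbers through, was not tested.

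For the counts of called genes chance could not be excluded either. Of the 35 splits of the deficient and heterozygous libraries, 3 called at least the 3 genes of the real split, and the highest other called 3091. That split set deficient replicates 1, 3 and 4 with heterozygous replicate 1 against the rest. Their recombination minus pluripotency differences were 0.04, -1.59, -0.36 and -1.72, below those of the rest (0.86 to 1.79). The split thus follows the first pattern, and it does not stand apart from genotype, since it keeps 3 of the 4 deficient libraries together. Of 100 splits for the contrast with the fertile genotypes, 8 called at least 1 gene, as the real split did, and the highest other called 698.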

How the results depend on the processing

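Alternatives with a meiotic stage covariate, a covariate of reads resembling ribosomal RNA, surrogate variables, doubted libraries left out, upper quartile scaling of lists, or pooled DESeq2 were tests chosen after the result was seen. Taf4b kept its direction against heterozygous, wildtype and fertile libraries in each alternative run, while counts of calls depended on the tool, the covariates and single libraries. The stage covariate is built from the pluripotency and recombination lists, so the loss of those list calls under it follows from its construction. The 2 least advanced libraries were chosen as the lowest in the difference of the same lists. Changes in those lists without them therefore follow in part from that choice. Stricter thresholds lower counts by construction. For the other changes the cause was not tested. Scaling moved the median of all genes by under 0.1, and no called list changed direction under the 3 other scalings. Simulated 1.5-fold changes were not recovered at this depth and number of libraries.

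Genes called in deficient against heterozygous libraries numbered 3, and 6 with DESeq2 size factors, upper quartile scaling or a minimum of 1 CPM in 4 libraries, 14 without a filter, 170 with DESeq2, 3012 with voom weights, and 97, 94 and 94 with TPM (pseudocount 0.1, 1, and 1 unfiltered; 89, 83 and 84 of them higher). They numbered 0 with litter date or at an adjusted p of 0.01, 6 with stage, 17 with the ribosomal RNA covariate, 7 and 143 with 1 and 2 surrogate variables, 97 without the 3 libraries low in Lars2 and Gm23935 (92 of them lower), and 13 without the 2 least advanced. Leaving out 1 library gave 0 to 519. Against wildtype the count of 0 became 1 without a filter, with DESeq2, voom, stage, 1 or 2 surrogate variables or without the 2 least advanced, 10 with unfiltered TPM, and 0 to 1 leaving out 1 library. Against the fertile genotypes the count of 1 became 4 with DESeq2, 7 with DESeq2 pooled, 11 with 2 surrogate variables, 0 with litter date, an adjusted p of 0.01, the 3 TPM settings, the ribosomal RNA covariate or without the 3 low libraries, and 0 to 1 leaving out 1. In heterozygous against wildtype libraries the count of 1 became 268 without a filter, 475 with DESeq2, 1063 with voom, 147 with only the groups compared, 0 with robust edgeR, litter date, an adjusted p of 0.01, filtered TPM, the ribosomal RNA covariate or 1 surrogate variable, and 14 with unfiltered TPM. It became 3 with stage, 123 with 2 surrogate variables, 186 without the 3 low libraries, 5 without the 2 least advanced, and 0 to 0 leaving out 1. X-linked calls went from 0 to 12 and 15 with DESeq2 in the comparisons of heterozygous with deficient and wildtype libraries, and ranged from 0 to 30 and 0 to 0 leaving out 1.

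The log2 fold change of Taf4b against heterozygous libraries missed the threshold at -1.83 with litter date and -1.71 at an adjusted p of 0.01, with a range of -1.80 to -1.59 leaving out 1 library. Against wildtype it passed at -1.55 without a filter, -1.56 with DESeq2, -1.58 with voom, -1.52 with stage, -1.54 and -1.47 with 1 and 2 surrogate variables and -1.60 without the 2 least advanced, with a range of -1.77 to -1.33. Against the fertile genotypes it missed at -1.64 with litter date, at an adjusted p of 0.01 and with the ribosomal RNA covariate, -1.71, -1.67 and -1.67 with TPM and -1.65 without the 3 low libraries, with a range of -1.74 to -1.498. In heterozygous against wildtype libraries the range was -0.06 to 0.34. Gm49450 reversed with TPM, to -1.91, -1.46 and -1.46. With the same settings Gm8226 lost its calls, at 0.62, 0.61 and 0.61 against 2.38 in deficient minus heterozygous (adjusted p = 0.06295, 0.05917 and 0.07781) and at -0.75 each against -2.59 in heterozygous minus wildtype (0.1063, 0.1055 and 0.1565).

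Lists called numbered 0 with an estimated correlation in the 3 comparisons that had any. Against wildtype the count of 0 became 2 with stage, without the 3 low or without the 2 least advanced libraries, and without the latter it became 11 against the fertile genotypes and 12 in heterozygous against wildtype. Leaving out 1 library gave 6 to 13, 0 to 4, 3 to 12 and 5 to 12 in the 4 comparisons. Upper quartile scaling ended the glycolysis call in deficient against heterozygous libraries (adjusted p = 0.05004) and called dissociation and immediate-early stress in heterozygous against wildtype (0.0451). A minimum of 1 CPM ended the calls of DNA replication (0.0521), glycolysis (0.0524) and cholesterol biosynthesis (0.0524) in the former and of stromal and mesothelial cell (0.440) in the latter. The stage covariate ended the calls of pluripotency and early germ cell (0.244), meiotic recombination (0.321), DNA replication (0.180), glycolysis and cholesterol biosynthesis (0.768 each) in deficient against heterozygous libraries. It also ended those of pluripotency and early germ cell (0.785), mitotic G2 and M phase (0.0527) and cytosolic ribosomal proteins (0.259) against the fertile genotypes, and of pluripotency and early germ cell, mitotic G2 and M phase, and p53 targets and apoptosis (0.0909 each) in heterozygous against wildtype libraries. Without the 3 low libraries meiotic recombination (0.174), glycolysis and cholesterol biosynthesis (0.0616 each) lost their calls in the first comparison and stromal and mesothelial cell (0.0759) in the last, and without the 2 least advanced the latter lost it too (0.196). Litter date also ended the call of p53 targets and apoptosis in heterozygous against wildtype libraries (0.183).

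Replicate numbers did not pair the libraries: deviations of the 8 same-numbered pairs correlated from -0.42 to 0.38, with a mean of -0.01. With the replicate block no gene was called in any of the 4 comparisons, Taf4b stood at -1.69 against heterozygous and -1.66 against fertile libraries, and 2 lists were called against wildtype where none had been. The block ended the call of the nuclear-encoded respiratory chain in heterozygous against wildtype libraries (0.1004).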

Other observations

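The tests of neighbours of Taf4b and of pseudogenes were set before their results were seen, while the look at Ddc, Sp3os and Aars2 was chosen after their values were.

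Among other subunits of TFIID no gene was called in any comparison by edgeR. Taf4, the ubiquitous relative of Taf4b, was at 7.16 ± 2.099 CPM in deficient, 6.56 ± 1.31 in heterozygous (SD, n = 4 each) and 6.92 ± 0.208 CPM in wildtype libraries (SD, n = 2), a log2 fold change of 0.12 against heterozygous libraries (SE 0.24, adjusted p = 0.835, edgeR). The list of TFIID subunits and TBP relatives was not called in any comparison (18 genes, median -0.03, adjusted p = 0.762 against heterozygous libraries). Within it the germ cell relatives Taf9b and Taf7l stood at -0.70 and -0.80 and Tbpl1, a TBP relative, at 0.39, each uncalled. Transcription factors of oocyte differentiation varied widely: Figla stood at 12.9 ± 9.98, 27.3 ± 16.8 and 15.4 ± 1.25 CPM, Nobox at 0.584 ± 0.332, 1.18 ± 0.232 and 0.671 ± 0.0142 CPM, and Sohlh1 at 1.19 ± 0.771, 1.09 ± 0.640 and 1.09 ± 0.147 CPM, in the same order. The receptor gene Kit stood at 606 ± 208, 530 ± 209 and 643 ± 63.7 CPM. The oocyte differentiation and primordial follicle list held 1 called member, Taf4b itself, and was not called (adjusted p = 0.911).

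Apart from blood and macrophage genes, no list of markers of other gonadal cells was called in deficient against heterozygous libraries. In that comparison the supporting (pregranulosa) cell list stood at a median of 0.21 (26 genes, adjusted p = 0.2003), with the keratin gene Krt18 at 49.8 ± 6.66 against 36.9 ± 7.78 CPM, the stromal and mesothelial cell list at 0.02 (adjusted p = 0.558), with the intermediate filament gene Vim at 0.94 and the basement membrane gene Col4a1 at -0.53, the endothelial cell list at 0.15 (adjusted p = 0.732), and the testis and male germ cell list at -0.15 (adjusted p = 0.732). The germ cell identity and piRNA pathway list stood at -0.12 (adjusted p = 0.689), with Mei1, needed for meiotic breaks, at -1.74 and Tdrd5, of the piRNA pathway, at 0.11. The DNA repair and Fanconi anaemia list stood at -0.04 (adjusted p = 0.732), with Rad51d at -0.53. The recombination initiator Spo11 stood at 30.01 ± 13.6, 50.4 ± 26.1 and 25.1 ± 3.83 CPM, and Lars2 at 7978, 9258 and 15568 CPM on average.

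A targeted allele carries linked sequence from its strain of origin, which could alter neighbours of Taf4b. Of 100 tested genes within 10 Mb of Taf4b, 2 (2.00%) had an unadjusted p under 0.05 against the fertile genotypes, compared with 4.31% of other genes. The odds ratio of 0.453 (95% interval 0.0540 to 1.68, Fisher's exact p = 0.451) argued against a broad excess of changed neighbours. It cannot exclude a few altered neighbours or small changes. Heterozygous libraries, which carry 1 mutant copy, enter the fertile mean, and simulated 1.5-fold changes were not recovered. The smallest adjusted p among them was 0.904.

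Gm8226 was low in heterozygous libraries alone, which raised the hypothesis that processed pseudogenes there may lose reads that belong to their parent genes. Over 240 pseudogenes with a tested parent, the median difference between pseudogene and parent log2 fold change (heterozygous minus the mean of the others) was 0.0851, with a 95% bootstrap interval of 0.0310 to 0.165. Pseudogenes had a median of -0.08 and parents of -0.26, so the pseudogenes did not track their parents exactly, nor did they fall below them. All 1769 tested processed pseudogenes had a median of -0.03. Neither outcome set in advance was met, and shared reads and a separate change of pseudogenes cannot be told apart.

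Ddc, Sp3os and Aars2 separated the 4 deficient from the 6 fertile libraries without overlap, as 283 of 20317 genes (1.39%) did where chance gives 0.952%, so their separation alone is weak evidence. Against the fertile genotypes DESeq2 called Ddc and Aars2, and with the fertile libraries pooled it called Ddc, Aars2 and Sp3os among 7 genes, while edgeR called none of them. With log2 fold changes of 0.67, 0.48 and -0.67 they would need a measurement in further embryos.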
